A study of Mus musculus with 2 samples.

How the data were processed

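The deposited counts of the authors were used, as 1 unfiltered matrix of raw UMI counts per library with 31053 genes and all barcodes, and no reads were processed here. Per the labels' protocols, libraries were made with 10x 3' v3.1 chemistry from kidney cortex digested with collagenase and protease at 37 °C. Reads had been counted against mm10 with Cell Ranger 3.1 and the later steps run in Seurat 3, per the submitters' processing notes. The matrix headers name Cell Ranger 4 instead, per the file headers, and this mismatch was left open. The matrices held 1737120 and 1979462 barcodes for PT I-PpoI and wild type, of which 1310593 and 1392615 had a UMI. Gene coordinates were taken from GENCODE M21, in which 30934 of the gene IDs were found.

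Cells were called from the unfiltered barcodes. A barcode was called if its UMI total reached the 99th percentile of the 3000 deepest barcodes divided by 10, which set thresholds of 5651 and 3655 UMIs. Barcodes of 500 or more UMIs, 7894 and 26640 in number, were also called if they differed from the ambient profile in a multinomial Monte Carlo test with 10000 simulations at a Benjamini-Hochberg rate of 0.01. The ambient profile was the sum of barcodes ranked 45001 to 90000 in depth, which held a median of 61 UMIs (12 to 77) in PT I-PpoI and 256 (14 to 333) in wild type. The first step called 4481 and 6471 barcodes and the second 2473 and 11375. Called barcodes with under 200 genes (586 and 2834) or over 50% mitochondrial UMIs (1752 and 5492) were left out, the 2 conditions overlapping. Scrublet, run through scanpy per library at an expected rate of 0.06, removed 81 (1.56%) and 288 (2.35%) doublets, which left 5121 and 11969 cells of 501 to 93775 and 500 to 61059 UMIs. Before doublets were removed, the barcodes left by these filters held 76.3% and 56.8% of all UMIs.

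Cells of both libraries were clustered together without batch correction, on 2000 variable genes, 30 components and 15 neighbours, with the Leiden method at resolution 1 (scanpy igraph implementation, 2 iterations, seed 7). A marker counted as detected in a cluster when it was read in 10% or more of its cells at 2-fold or more over the mean of the other clusters. A cluster was named after the class with the highest mean standardised marker level among those with 3 or more detected markers, or as cycling where cell cycle markers prevailed among its 10 leading genes. It stayed unnamed where those leading genes held more markers of another class, or where it was shallow and they held none of its own. Markers rest on reference knowledge, so classes are called PT-like and so on. Raw UMIs were summed over the cells of a class per library and scaled to CPM. Ratios carry a prior of 0.5 count and exact conditional binomial 95% intervals, sums carry Poisson intervals and shares Clopper-Pearson intervals. For a share of 0 the limit given is 3 counts of the total, which lies below the Clopper-Pearson upper limit. A list median used members with 10 or more UMIs over both libraries and was placed among 10000 random lists of the same size matched on expression in 20 bins. Its interval was a binomial 95% interval taken from the ranked ratios of its members, so it measures the spread among members. Classes with 50 or more cells in each library were compared, and 31 gene lists were used. TMM factors came from edgeR on the class sums and are reported as the shift they give to all ratios, with no edgeR test run.

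PT genes were named by a rule. It took genes of 50 CPM or more in the higher library, with the same sign in every PT-like cluster holding 100 or more cells of each library (cluster 14 alone) and after subtraction of free RNA. It took the 12 largest and 12 smallest ratios and left out mitochondrially encoded, ribosomal protein, haemoglobin, immunoglobulin and Y-linked genes, Xist and unnamed gene models. In macrophage, T or NK, endothelial and thick ascending limb classes 4 genes each way were taken at 100 CPM and 20 UMIs or more, with most of the UMIs of the higher library left after subtraction. Up to 4 members per list were named, being those furthest from 0 with 30 or more UMIs in the higher library. Coordinates and a second look at single clusters were given only for genes named by the rule or held in the fixed lists. Some genes taken by these rules are not reported. A value of 0 was replaced by a floor of 3 counts to give a fold as a minimum. For shares of cells with a UMI, cells were thinned to 2000 UMIs.

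Free RNA was estimated for each class from genes of other classes. It came to 3.16% and 26.0% of PT-like UMIs, 2.91% and 13.2% in cluster 14, 4.65% and 19.4% in T or NK cells, 7.51% and 18.6% in endothelium, 4.67% and 11.2% in the thick ascending limb, and 23.6% and 71.3% in mural cells, where values are the least certain. It was subtracted only as an alternative. A second profile came from barcodes of 100 or fewer UMIs, because the wild-type ranks used as ambient were deep and took 39.98% of their UMIs from Gm42418, against 5.11% in those barcodes. Whether these ranks hold free RNA or damaged cells was not settled, so the free RNA shares and subtracted values of wild type are uncertain.

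A self-test used made-up counts. Class sums were drawn as independent Poisson counts, the model that the ratio intervals and random lists assume, so the ratio and list part checked the code only. It did not check how well the intervals cover UMIs gathered in few cells. Of 1000 barcodes drawn from the ambient profile, the model under test, 0.3% and 0.5% were called. Of 1000 with 20% of another profile, which was the ambient profile shuffled over genes, 100% were called. A shuffled profile is far from the ambient one, so this part also checked the code only, not the calls of real barcodes. Ratio intervals covered the known value for 96.5% of 200 altered genes in the PT class, 97% in macrophages, 98% in T or NK cells, 96.5% in endothelium and 96% in the thick ascending limb, with the right sign for 99% to 100% of them. From 3 to 5 of 100 unaltered lists lay outside the 95% range of random lists.

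Filters, comparisons, gene lists, the rule for naming genes and the alternatives not named as added were set before the data were examined. The number of variable genes, components, neighbours and simulations, the expected doublet rate, the thinning depth, the thresholds for naming clusters and the limits for naming list members were not. The alternatives covered cell calling, UMI minimum, mitochondrial limit, doublets, clustering, normalization, free RNA, mitochondrial UMIs, list filters, thinning and the prior. Added alternatives are listed as such in the part on how the results depend on the processing, and are not marked each time a value is given. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16. Sex, strain and number of animals per library were not given in the sources used here.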

Results

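Single-cell RNA was counted from the kidney cortex of mice at 16 weeks, with 1 library from a PT I-PpoI kidney and 1 library from a wild-type kidney. I-PpoI is a homing endonuclease that makes DNA double-strand breaks, and per the series title it was expressed in the proximal tubule (PT) epithelium. The PT I-PpoI library held 93257620 unique molecular identifiers (UMIs) and the wild-type library held 107977310. Barcodes called as cells numbered 6954 and 17846, and 5121 and 11969 cells were kept after filtering. Kept cells were deeper in PT I-PpoI, with a median of 11065 UMIs and 3023 genes per cell against 2684 UMIs and 1082 genes. Median mitochondrial shares were 11.7% and 15.3%. All values below are given as PT I-PpoI first and wild type second, and ratios are PT I-PpoI over wild type on the log2 scale. Levels are in CPM, the UMIs of a gene per 1000000 UMIs of its class and library. With 1 library per group no test between groups was possible, and no interval covers differences between animals. Intervals of sums, ratios and shares cover counting error only. Intervals of list medians cover the spread among list members, taken as independent, and not counting error. Intervals of sums and ratios treat UMIs as independent, so they are too narrow where a few cells hold many UMIs of a gene. The feature list held 0 entries for I-PpoI or a Cre recombinase, so expression of the transgene itself could not be read.

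**Figure D1:**
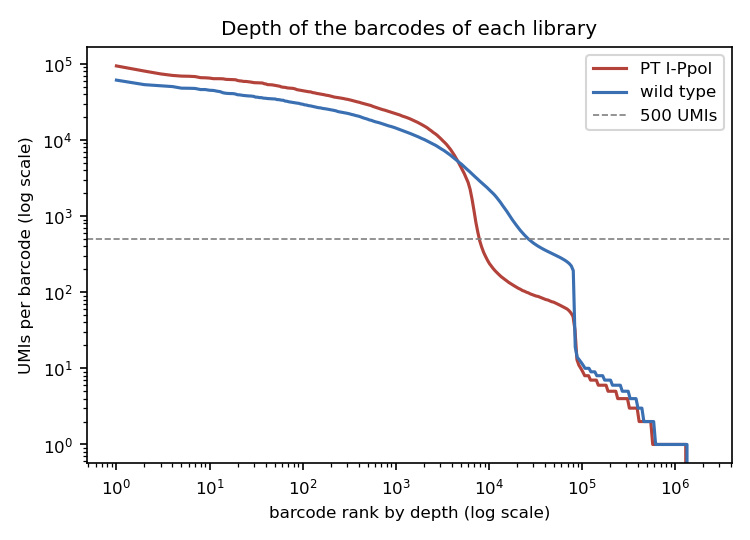
UMIs per barcode against barcode rank for both libraries on log scales. The dashed line marks the minimum of 500 UMIs.

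PT-like cells, which carry out most reabsorption in the kidney, made up 3.32% (2.85 to 3.85) of PT I-PpoI cells and 40.04% (39.2 to 40.9) of wild-type cells, or 170 and 4792 cells. They lay in clusters 8, 9, 14, 30, 31, 33 and 34. Cluster 14, led by the early-segment transporters Slc5a12 and Slc5a2 and the amino acid transporter Slc6a19, held 67.1% of PT-like cells in PT I-PpoI and 19.5% in wild type. Cluster 33, led by Kap and Inmt, held 3 and 1042 cells, and cluster 34, led by Napsa and Slc22a7, held 1 and 262 cells. Cluster 30, led by the late-segment carriers Slco1a1 and Slc7a13, held 8 and 743 cells. Thick ascending limb cells were the largest class of PT I-PpoI at 28.0% (26.8 to 29.3), against 8.57% (8.08 to 9.09). Distal convoluted tubule cells stood at 11.2% and 2.10%, connecting tubule cells at 4.20% and 0.969%, principal cells at 8.63% and 1.50%, and intercalated cells at 6.95% and 2.12%. Unnamed clusters held 8.20% and 15.7% of cells. Among these, cluster 10 held 0 and 1108 cells and had 14 PT markers above the rule, cluster 11 held 304 and 381 cells, cluster 17 held 111 and 249, and cluster 32 held 5 and 145. A cluster made mostly of 1 library may be a property of that library, and all shares were taken above a minimum of 500 UMIs between libraries of unequal depth.

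**Figure D2:**
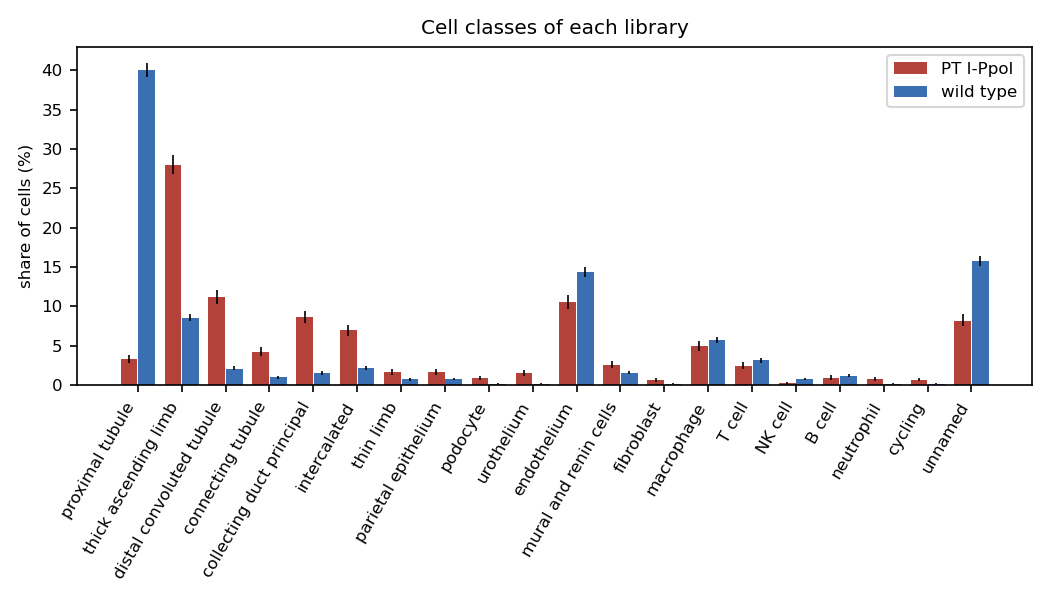
Share of each cell class among the cells of each library. T and NK cells are drawn separately.

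Because a low PT share raises all the others, shares were also taken of named cells outside the PT, 4531 in PT I-PpoI and 5294 in wild type. Endothelial cells were 11.9% (10.97 to 12.9) and 32.5% (31.2 to 33.8) of these, without the unnamed cluster 11 (304 and 381 cells), whose closest class was endothelium, and immune cells 10.6% (9.71 to 11.5) and 24.8% (23.7 to 26.0), without the unnamed cluster 17 (111 and 249 cells), whose closest class was conventional dendritic cells. Thick ascending limb cells remained the larger share in PT I-PpoI, at 31.7% (30.3 to 33.0) and 19.4% (18.3 to 20.5), as did distal convoluted tubule cells at 12.6% and 4.74% and principal cells at 9.76% and 3.40%. Parietal epithelium (1.88% and 1.66%), thin limb (1.88% and 1.61%) and mural cells (2.91% and 3.51%) differed little. Within named immune cells, macrophages made up 52.9% (48.3 to 57.5) and 52.1% (49.4 to 54.8), and T cells 26.2% (22.4 to 30.4) and 28.6% (26.2 to 31.1). Neutrophils were 8.54% (6.20 to 11.4) and 1.75% (1.11 to 2.61) of immune cells, natural killer cells 2.5% (1.30 to 4.33) and 7.07% (5.75 to 8.59), and B cells 9.79% and 10.5%.

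In PT-like cells Ptgds, which makes prostaglandin D, had the largest higher value in PT I-PpoI by the named-gene rule, with 279 and 4.52 CPM, a log2 ratio of 5.94 (5.68 to 6.22). Sparc, a matrix-binding glycoprotein, stood at 130 and 13.6 CPM, a ratio of 3.27 (3.04 to 3.49). The inducible heat-shock chaperone genes Hspa1a (125 and 18.2 CPM, 2.79) and Hspa1b (117 and 17.9 CPM, 2.71), which 3' reads may not separate from each other, were also higher. Jun, a subunit of an early-response transcription factor, stood at 496 and 97.4 CPM, 2.35 (2.24 to 2.45). The signalling GTPase gene Rhob (2.56), the transcription factor gene Klf6 (2.16), the protease inhibitor gene Serpinb6a (2.13) and the scaffold gene Magi2 (2.06) followed. Further higher genes were interferon-inducible Ifi27 (1.97), the vitamin D-binding protein gene Gc (1.962) and the serine synthesis gene Phgdh (1.95). In cluster 14 alone Ptgds stood at 5.58, Sparc at 2.46, Hspa1a at 2.45, Jun at 1.51 and Ifi27 at 1.43. Ptgds is ENSMUSG00000015090 (mm10 chr2, 25466709 to 25470046), Hspa1a is ENSMUSG00000091971 (chr17, 34969190 to 34972156) and Jun is ENSMUSG00000052684 (chr4, 95049034 to 95052222). Trimmed mean of M-values (TMM) factors shifted every ratio of this class by −0.29, and relative to that shift Ptgds stood at 5.65, Jun at 2.06 and Phgdh at 1.66.

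Among genes lower in PT I-PpoI, the fatty acid omega-hydroxylase gene Cyp4a14 had the smallest ratio by the same rule. It had 3 and 1882 UMIs in PT-like cells (1.46 and 58.2 CPM), a ratio of −5.10 (−7.60 to −3.77). Lipoprotein lipase gene Lpl (144 and 699 CPM, −2.28), the monoacylglycerol transferase gene Mogat1 (−2.60) and Cyp4a10 (31.1 and 167 CPM, −2.41) were lower too. Transport genes included Slc13a3 for dicarboxylates (36.0 and 222 CPM, −2.61) and Slc22a6 for organic anions (108 and 570 CPM, −2.40). The hydroxylase genes Cyp2a5 (−3.61) and Cyp2a4 (−2.78), a pair that reads may not separate, the meprin gene Mep1b (−2.35), the aspartic protease gene Napsa (−2.21) and the androgen-regulated gene Kap (6535 CPM in PT I-PpoI, −2.23) were lower as well. In cluster 14 alone Cyp4a14 had 0 and 90 UMIs, at least 4.43-fold lower. Slc13a3 stood at −3.46 there, Slc22a6 at −2.48, Lpl at −2.43, Cyp4a10 at −2.44 and Kap at −3.05. After free RNA was subtracted Kap stood at −1.59 in cluster 14, so much of its difference there may be free RNA of wild type. The markers of the second PT segment, Slc22a6 and Slc13a3 among them, had a median of −1.80 within cluster 14, and those of the first segment 0.01. Kap leads cluster 33, Slc22a6 is among the leading genes of cluster 30 and Napsa, Mep1b and Cyp2a4 are among those of cluster 34. Cyp4a14 is ENSMUSG00000028715 (mm10 chr4, 115486200 to 115496142), Slc22a6 is ENSMUSG00000024650 (chr19, 8618039 to 8628299) and Kap is ENSMUSG00000032758 (chr6, 133849851 to 133853762). Mep1b had 0 and 7 UMIs in cluster 14 and turned to 2.60 there after free RNA was subtracted, so its value rests on the whole class.

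Of the lists closest to DNA damage in PT-like cells, p53 targets were higher by a median of 0.45 (0.22 to 0.96), with 23 genes higher and 6 lower. This lay at percentile 73.5 of random lists of matched expression and at 0.16 relative to the TMM shift. Percentiles here place a list among random lists of these libraries and are not tests. The largest members were Plk3 (15.1 and 2.69 CPM, 2.501), Ddit4l (1.93), Btg2 (26.7 and 7.18 CPM, 1.91) and Pmaip1 (1.71). Btg2 is also a member of the list of immediate early and dissociation genes given below, so it does not tell these lists apart. The cell cycle arrest gene Cdkn1a stood at 17.5 (12.3 to 24.2) and 9.10 (8.09 to 10.2) CPM, 0.96, while Mdm2 (0.40), Ccng1 (0.26) and Gdf15 (0.76) were nearer. In cluster 14 the p53 median was 0.52 at percentile 99.7, with Ddit4l at 3.44, Btg2 at 2.17 and Cdkn1a at 1.46. Non-homologous end joining genes stood at 0.70 (percentile 97.7, 0.41 relative), led by Paxx (0.88), Parp1 (0.79) and Prkdc (0.70), and at 0.34 (percentile 74.7) in cluster 14. Homologous recombination genes stood at 0.43 (percentile 45.0, 0.14 relative), with Rbbp8 at 0.98 and Rad50 at 0.88. Cell cycle genes stood at 0.52 (percentile 79.6), senescence genes at 0.52 (percentile 84.4) with Cxcl16 at 1.47 and Igfbp5 at 1.07, and apoptosis genes at 0.49 (percentile 83.6) with Mcl1 at 0.93. DNA methylation and demethylation genes stood at 0.74 (percentile 99.3), with Gadd45a at 1.58 and Dnmt3a at 0.94. Nucleolar genes stood at 0.24, and at −0.05 relative to the TMM shift, with the polymerase factor Rrn3 at 1.04.

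Tubular injury genes had a median of 0.75 (0.38 to 1.95) in PT-like cells, percentile 99.6, with complement C3 (17.0 and 2.75 CPM, 2.64), the galectin gene Lgals3 (2.42) and secreted Spp1 (1.48) higher and the chaperone gene Cryab (−1.97) lower. This median was 1.24 in cluster 14, with C3 at 2.502 and S100a6 at 2.12, and 1.84 with the libraries clustered separately. It was 0.46 relative to the TMM shift and 0.48 with free RNA subtracted. With the profile of barcodes of 100 or fewer UMIs subtracted it was 0.43. The classic injury gene Havcr1 had 0 and 3 UMIs. Immediate early genes stood at 1.38 (1.03 to 1.86), percentile 100, with Klf4 at 24.3 and 1.67 CPM (3.86), and 1.17 in cluster 14. Interferon response genes stood at 1.33 (0.84 to 1.76), percentile 99.99, with the RNA sensor Ddx58 (28.2 and 8.38 CPM, 1.76) and Stat2 (1.30) higher. That median was 0.83 in cluster 14 and 0.69 as a mean over cells. Genes of NF-kB signalling stood at 0.96 (percentile 97.4, Nfkbiz 1.85), MHC class I genes at 0.73 (percentile 99.5, H2-K1 0.90, B2m 0.84, H2-T22 −0.96) and MHC class II genes at 0.35 (percentile 48.6). Endothelial activation genes read in these cells stood at 0.80 (percentile 96.6) and matrix genes at 0.44 (percentile 61.8).

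Fatty acid oxidation genes were lower in PT-like cells of PT I-PpoI, by a median of −0.48 (−0.89 to −0.12), with 9 higher and 27 lower, percentile 0, and −0.77 relative to the TMM shift. The peroxisomal thiolase gene Acaa1b stood at 110 and 346 CPM (−1.65) beside Cyp4a14. In cluster 14 the median was −0.18, also at percentile 0. PT identity genes stood at −0.15 (−0.78 to 0.17), −0.44 relative, with the cystine carrier gene Slc7a13 at −1.83 and the brush border enzyme gene Ggt1 at −1.75. Sex-dependent genes stood at −1.25 (−1.66 to 0.14), percentile 0, and −1.38 in cluster 14. Slc7a12 had 0 and 190 UMIs, at least 4.03-fold lower, while the carrier gene Slc22a29 was higher (2.16). Other metabolic lists differed less, with glycolysis at 0.29 (Pfkp 1.68, Pkm 1.41), which was 0.00 relative to the shift, gluconeogenesis at −0.02 (Pck1 −0.83), cholesterol synthesis at 0.06 (Ebp −1.25, Fdps 1.05), nuclear oxidative phosphorylation at −0.03 and mitochondrially encoded genes at −0.12. Ribosomal protein genes stood at −0.10, and at 0.28 in cluster 14. Oxidative stress genes stood at −0.12 (Nqo1 −1.16, Gclc −1.04, Gsta4 1.28) and unfolded protein response genes at 0.10 (Ddit3 0.97, Xbp1 −0.69). Lists made for other cells gave 0.20 for macrophage lipid and repair genes (Apoe 1.91), −0.42 for macrophage inflammatory genes and −0.42 for T cell activation. The 4 globin genes read in these cells had 0 UMIs in PT I-PpoI, with Hbb-bs at 0 and 434, at least 9.20-fold lower. This held for the whole library, as Hbb-bs had 1 and 5662 UMIs over all barcodes.

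**Figure D3:**
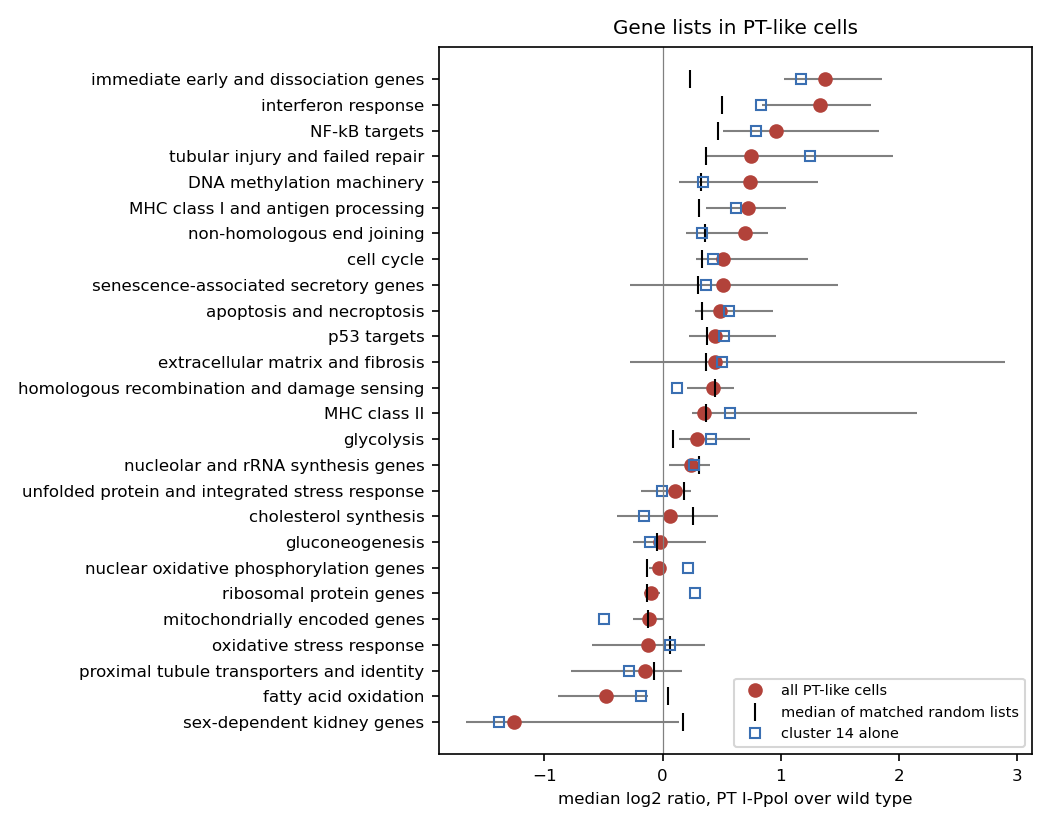
Median log2 ratio of gene lists in PT-like cells and in PT-like cluster 14. Haemoglobin, T cell activation, endothelial activation and both macrophage lists are left out.

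Shares of PT-like cells with a UMI were taken after thinning each cell to 2000 UMIs, which left 164 and 3610 cells and left out 6 and 1182 as too shallow. Median depths before thinning were 10829.5 and 4381.5 UMIs. Spp1, an injury-associated secreted protein, was read in 68.3% (60.6 to 75.3) and 36.2% (34.6 to 37.8) of cells, with 19.1% and 9.52% of T or NK cells as the comparator and 89.4% and 50.4% unthinned. Keratin gene Krt8 was read in 17.1% (11.7 to 23.7) and 11.7% (10.7 to 12.8), with 0.763% and 1.40% in T or NK cells and 46.5% and 26.6% unthinned. The p53 target Mdm2 was read in 11.6% (7.12 to 17.5) and 5.48% (4.76 to 6.28), of which the wild-type value lay below its comparator (7.63% and 8.96%, unthinned 32.4% and 15.3%). Cdkn1a at 1.83% and 1.27% lay below the T or NK share of 3.82% and 3.64% in both libraries, with 8.82% and 4.15% unthinned. Cdkn1a, Mdm2 and Ccng1 are also expressed in lymphocytes, so for these the T or NK share is not a measure of background. Ccng1 was read in 9.15% and 9.94% (comparator 5.34% and 8.40%, unthinned 40% and 24.7%). Gdf15 was read in 2.44% and 3.24%, against a comparator of 0 that allows up to 2.29% and 0.840%. By Clopper-Pearson the comparator allows up to 2.78% and 1.03%, so the PT I-PpoI share does not stand above it. Unthinned, Gdf15 was read in 15.3% (10.2 to 21.6) and 7.10% of PT-like cells, against 0 of 138 T or NK cells in PT I-PpoI, which allows up to 2.17%, and 0.213% in wild type. Havcr1 was read in 0 of the thinned cells, which allows a share of cells with a UMI of up to 1.83% and 0.0831%. Unthinned, Havcr1 was read in 0 of 170 cells and 3 of 4792 cells. Krt18, Clu, Vcam1, Lcn2, Phlda3 and Eda2r were each read in 1.83% or less of the thinned cells of either library.

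In macrophages the chemokine gene Cxcl9, which draws T cells and is induced by interferon gamma, stood at 351 and 26.0 CPM, a ratio of 3.74 (3.35 to 4.19). The small heat-shock gene Hspb1 stood at 211 and 13.004 CPM, 3.99 (3.45 to 4.64), the chaperone gene Dnajb1 at 608 and 84.3 CPM, 2.85, and the transglutaminase gene F13a1 at 108 and 14.4 CPM, 2.89. MHC class I genes were higher by a median of 0.74 (0.65 to 0.90), with 20 higher and 0 lower at percentile 100, led by the peptide transporter genes Tap1 (110 and 40.5 CPM, 1.43) and Tap2 (1.21). Interferon response genes stood at 0.50 (0.16 to 0.61), percentile 100, with Ifi44 at 68.4 and 6.74 CPM (3.30). Cell cycle genes stood at 1.16 (0.68 to 1.41) with Pcna at 1.41, lipid and repair genes at 0.37 with the folate receptor gene Folr2 at 3.19 and Cd163 at 1.45, and inflammatory genes at 0.23 with Ccl2 at 210 and 46.2 CPM (2.18). TMM shifted this class by −0.12, leaving MHC class I at 0.62 and interferon at 0.38, and ribosomal protein genes turned to −0.02. Genes lower in PT I-PpoI were the prostaglandin dehydrogenase gene Hpgd (215 and 524 CPM, −1.28) and the distal tubule transcripts S100g (−2.18), Klk1 (−2.27) and Calb1 (−1.14), of which Klk1 (0.04) and Calb1 (0.91) turned positive at a mitochondrial limit of 30%. Free RNA made up 6.44% and 20.3% of macrophage UMIs. Cxcl9 is ENSMUSG00000029417 (mm10 chr5, 92321347 to 92328079).

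T or NK cells of PT I-PpoI carried more proliferation transcripts. Cell cycle genes were higher by a median of 1.40 (0.97 to 1.68), with 20 higher and 0 lower, led by the microtubule gene Stmn1 (331 and 82.5 CPM, 1.9996), the replication helicase genes Mcm5 (1.88) and Mcm3 (1.57) and Mki67 (61.5 and 20.6 CPM, 1.57). In the T cell cluster alone this median was 1.16 (0.95 to 1.36), and the replication clamp-binding gene Pclaf stood at 142 and 30.2 CPM in the whole class (2.22). The heat-shock genes Hspa1a (1209 and 69.2 CPM, 4.12) and Hspa1b (745 and 59.7 CPM, 3.63) were the largest named values. T cell activation genes had a median of 0.25 (−0.11 to 0.71), percentile 82.1, with interferon gamma gene Ifng at 656 and 242 CPM (1.43), checkpoint receptor gene Ctla4 at 1.40 and granzyme gene Gzmb at 296 and 125 CPM (1.24). Water channel gene Aqp1 stood at 2.68 but at −1.40 in the T cell cluster alone, and Cryab at −4.93 but at 0.28 there. The lower genes Esm1 (−5.62) and Meis2 (−5.54), which are not lymphocyte genes, rested on 2 and 1 UMIs in PT I-PpoI, and in the T cell cluster alone stood at −2.70 (−6.12 to −0.99) and −1.85 (−7.82 to 0.55).

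Endothelial cells, in cluster 12 (397 and 1412 cells), cluster 19 (84 and 276) and the arterial-like cluster 25 (58 and 31), had higher fibronectin, filament and heat-shock transcripts in PT I-PpoI, while the matrix list did not differ (0.00, with 9 higher and 8 lower, and −0.21 relative to the TMM shift). Cluster 25 was also deeper, with a median of 9836 UMIs against 2181 in cluster 12. No values were taken within single endothelial clusters, so another mix of vessels cannot be told apart from changed levels. Fibronectin gene Fn1 stood at 105 and 12.3 CPM (3.08), the filament gene Vim at 1758 and 258 CPM (2.77), Hspa1a at 2234 and 309 CPM (2.85) and the tetraspanin gene Tspan8 at 224 and 26.7 CPM (3.07), which turned to −1.01 with the libraries clustered separately. TMM shifted the class by −0.21, leaving Fn1 at 2.87, Vim at 2.56 and Hspa1a at 2.64. Immediate early genes stood at 0.98 (0.68 to 1.15; 0.77 relative) with Socs3 at 2.01 and Junb at 1.55, injury genes at 0.73 (0.52 relative) with Ccl2 at 2.90, and senescence genes at 0.58 (0.37 relative) with Mmp2 at 2.94. Activation genes stood at 0.37 (0.16 relative), with endothelin gene Edn1 at 215 and 65.2 CPM (1.72) and Vwf at 1.48 higher and the adhesion receptor gene Sele (−1.71) and Aplnr (−1.29) lower. MHC class II genes were lower, −0.45 with 0 higher and 8 lower. The p53 list stood at 0.23 and at 0.02 relative, although Phlda3 was 82.0 and 25.9 CPM (1.66) and Gdf15 had 59 and 3 UMIs (4.44). Lower named genes were Fmo1 (−0.90), the cell cycle regulator Rgcc (660 and 1181 CPM, −0.84), St6galnac3 (−0.73) and Cpne2 (−0.72).

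Thick ascending limb cells differed less, although they were spread differently over clusters (cluster 1 with 1067 and 414 cells, cluster 2 with 39 and 506, cluster 4 with 329 and 106). Hspa1a stood at 235 and 61.4 CPM (1.93), Hspa1b at 1.79, glutathione reductase gene Gsr at 122 and 49.4 CPM (1.30) and the RNA-binding gene Hnrnpa0 at 0.90. Lower genes were the oxidase subunit gene Cyba (−1.02, but 0.30 with the profile of barcodes of 100 or fewer UMIs subtracted), Ndrg1 (−0.90) and the calcium-binding gene S100g (125 and 429 CPM, −1.78), which turned to 2.08 at a mitochondrial limit of 30%. TMM shifted the class by −0.11. The p53 list stood at 0.06 (percentile 27.0) with Gdf15 at 13.8 and 2.76 CPM (2.27), the immediate early list at 0.02 and the DNA methylation list at 0.37 (percentile 99.9).

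Across classes the heat-shock gene Hspa1a was higher in PT I-PpoI in all of them, from 4.12 in T or NK cells, 3.34 in parietal epithelium and 3.31 in mural cells to 1.09 in the distal convoluted tubule. Immediate early genes did not follow it, with 1.38 in PT-like cells, 0.98 in endothelium, 0.71 in mural cells, 0.66 in T or NK cells and 0.60 in macrophages, but −1.26 (−1.51 to −0.33) in the distal convoluted tubule. There Fos stood at 177 and 740 CPM (−2.06), Egr1 at 28.0 and 164 CPM (−2.55) and Socs3 at −3.20. Interferon response genes were highest relative to wild type in PT-like cells (1.33) and the connecting tubule (0.91), then intercalated cells (0.54), macrophages (0.50) and principal cells (0.47), and lower in the distal convoluted tubule (−0.70). Mitochondrially encoded genes were lower in macrophages (−1.36), T or NK cells (−1.40) and endothelium (−1.12). With the profile of barcodes of 100 or fewer UMIs subtracted these stood at −0.15, 0.0748 and −0.28. That profile was 24.5% mitochondrial in PT I-PpoI and 46.2% in wild type, against 16.2% and 21.4% in the ambient ranks, so the size of this move is uncertain. PT identity genes read in other classes, a measure of free PT RNA, were lower by −3.40 in the thick ascending limb to −4.66 in principal cells.

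**Figure D4:**
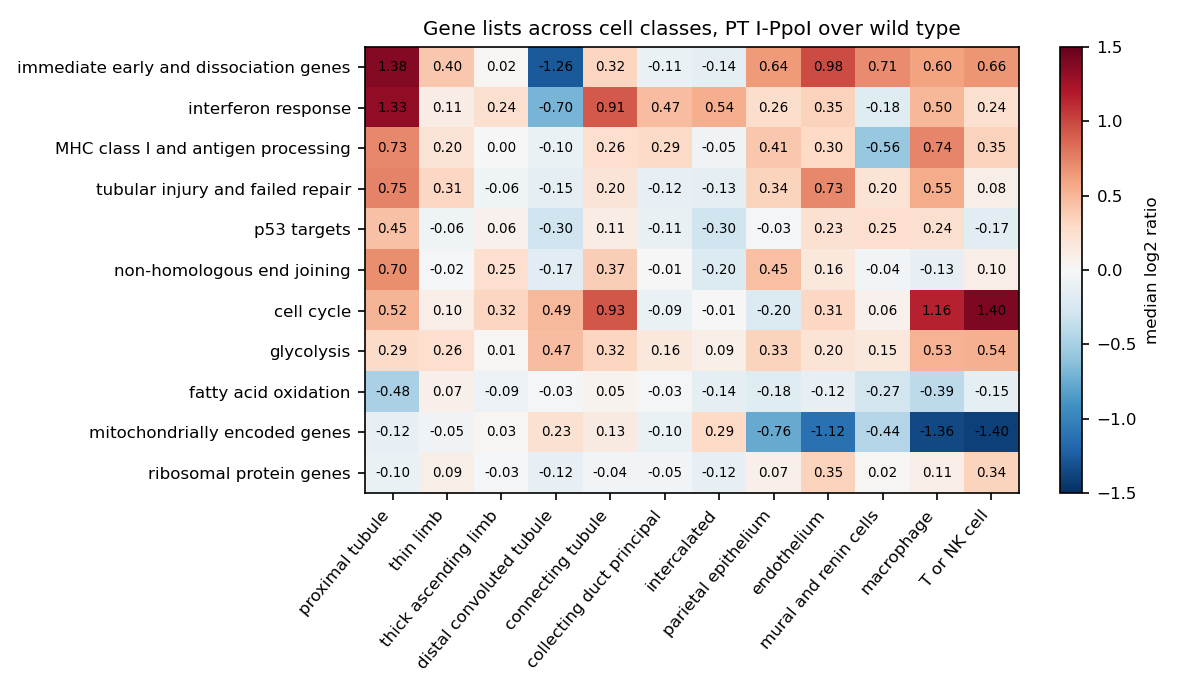
Median log2 ratio of gene lists in each cell class, PT I-PpoI over wild type.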

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

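All tests in this part were chosen after the result was seen. Immediate early and dissociation genes pointed in opposite directions between cell classes, at 1.38 in PT-like cells and −1.26 in the distal convoluted tubule, and the difference was not tested. The 7 heat-shock members had medians of 0.02 in PT-like cells and −0.21 in the distal convoluted tubule, and the other 18 members 1.43 and −1.41. A second value came from barcodes outside the main measurement. Called barcodes with 90% or more mitochondrial UMIs were 13.4% (12.6 to 14.2) of those called in PT I-PpoI and 2.29% (2.07 to 2.52) in wild type. PT markers made up 2.76% of the non-mitochondrial UMIs of these barcodes in PT I-PpoI, against 0.247% to 1.16% at lower mitochondrial shares. In wild type they made up 4.17% of such barcodes, against 2.05%, 6.35% and 5.74% at lower mitochondrial shares, so the order seen in PT I-PpoI did not hold there.

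The low PT-like share of PT I-PpoI was weighed against 3 technical explanations. Removal of intact PT barcodes by calling and the mitochondrial limit would leave the PT marker share of all UMIs alike. That share was 0.550% in PT I-PpoI and 3.18% in wild type, 5.79 times higher (5.77 to 5.80), which argues against such removal as the whole cause. PT barcodes that had lost most of their other RNA would add little to this share, so it cannot decide for them. The 932 PT I-PpoI barcodes of 90% or more mitochondrial UMIs held only 259707 non-mitochondrial UMIs, so their removal stays open. PT cells that broke open and left their RNA in the suspension would raise PT markers in free RNA. Barcodes of 100 or fewer UMIs held 0.806% and 2.90%, 3.599 times more in wild type (3.56 to 3.64). That cut takes in the ambient ranks of PT I-PpoI but leaves out most of those of wild type, so the 2 sets are unlike. In the ambient ranks the shares were 0.879% and 2.83%, again higher in wild type, although whether the wild-type ranks hold free RNA was not settled. Both values argue against breakage as the whole cause. In PT I-PpoI both shares were above that of all its UMIs, so some breakage stays open. A piece of tissue with more medulla or pelvis cannot be told apart, because distal convoluted tubule cells per thin limb cell were 2.28 times higher in PT I-PpoI (approximate 1.63 to 3.19) while urothelium cells per thin limb cell were 4.53 times higher. Loss of PT cells through the induced breaks could give the same low share and was not tested.

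Hspa1a and Hspa1b were higher in PT-like cells. Handling or dissociation stress that reached the whole library fits for Hspa1a, whose interval lay above 0 in 11 of 11 other compared classes. Other stress genes followed it in some classes only, as the immediate early and dissociation list was higher in endothelium (0.98) and macrophages (0.60) but stood at 0.02 in the thick ascending limb and −1.26 in the distal convoluted tubule, and the 7 heat-shock members had a median of 0.02 in PT-like cells. Free RNA does not explain it well, because the smallest Hspa1a ratio over all classes was 0.91 after subtraction, in the distal convoluted tubule. A stress response of the whole kidney to PT damage might give the same pattern and was not tested.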

How the results depend on the processing

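Over 247 results, 3260 alternative values were computed, of which 2774 kept direction and interval, 455 moved outside the interval and 31 changed sign. For shares 57 of 112 values kept and 55 moved, for list medians 2109 of 2312 kept, 186 moved and 17 changed sign, for shares of cells with a UMI 30 of 52 kept and 22 moved, and for named genes 578 of 784 kept, 192 moved and 14 changed sign. For list medians the interval was the spread among members, not counting error. The 24 named PT genes were selected for 1 sign in the whole class, in cluster 14 and after subtraction of free RNA, so those settings could not turn them, and none turned under the others. The 10 results followed most closely (both PT shares, 5 PT lists, macrophage MHC class I and interferon, T or NK cell cycle) were chosen after their values were seen. Alternatives chosen after seeing the data were the mitochondrial limit of 80%, deep barcodes only, the S1-like cluster 14 alone, the T cell cluster alone and the profile of barcodes of 100 or fewer UMIs. The cause was not tested for any of these moves. No paired analysis was possible because each group had 1 library and no labels link them.

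The wild-type PT share was 37.2% with all barcodes of 500 UMIs, 45.9% at a UMI minimum of 1000, 33.5% at a mitochondrial limit of 30% and 46.4% at 80%, 37.7% with doublets kept, 49.5% at resolution 0.5, 48.8% with separate clustering and 55.2% with deep barcodes only. The PT I-PpoI share was 4.42% at the limit of 80%. With TMM factors PT p53 targets stood at 0.16, PT nucleolar genes at −0.0523, macrophage MHC class I at 0.62, macrophage ribosomal protein genes at −0.0159, and endothelial oxidative phosphorylation at −0.0882, glycolysis at −0.0104 and nucleolar genes at −0.0187. With free RNA subtracted PT immediate early genes stood at 2.06, macrophage MHC class I at 0.57, macrophage ribosomal protein genes at −0.0694, and endothelial oxidative phosphorylation at −0.0441 and glycolysis at −0.0153. With the profile of barcodes of 100 or fewer UMIs, these were 2.71 (PT immediate early), 0.61 (macrophage MHC class I) and −0.0195 (macrophage ribosomal), with T or NK mitochondrially encoded genes at 0.0748 and thick ascending limb Cyba at 0.30. As means over cells PT interferon genes stood at 0.69, macrophage Calb1 at 0.0381 and thick ascending limb matrix genes at 0.0591. In cluster 14 PT interferon genes stood at 0.83 and ribosomal protein genes at 0.28.

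With deep barcodes only macrophage interferon stood at 0.67 and MHC class I at 1.01, T or NK cell cycle at 1.80, oxidative phosphorylation at −0.0777 and cholesterol synthesis at −0.27, endothelial oxidative phosphorylation at −0.0437, and thick ascending limb MHC class II at 0.10 and S100g at 0.0714. Without mitochondrial UMIs macrophage MHC class I stood at 0.64. S100g of the thick ascending limb stood at 0.37 with all barcodes of 500 UMIs, 2.08 at a mitochondrial limit of 30%, 0.14 at 80% and 0.64 with doublets kept. Macrophage Klk1 stood at 0.0398 and Calb1 at 0.91 at the limit of 30%, and Calb1 at 0.23 with doublets kept, where endothelial oxidative phosphorylation stood at −0.0948. With separate clustering T or NK Aqp1 stood at −1.23 and endothelial Tspan8 at −1.01. In the T cell cluster alone Aqp1 stood at −1.40 and Cryab at 0.28.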

Other observations

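All tests in this part were chosen after the result was seen. Interferon genes were also higher in some classes outside the PT in PT I-PpoI, but not in the distal convoluted tubule (−0.70) or mural cells (−0.18). In intercalated cells, which secrete acid or base, Ifit3 had 51 and 3 UMIs (2.45), Ifit1 stood at 1.84 and Isg15 at 1.65, while in the connecting tubule Ifit1 had 32 and 1 UMIs, 3.01 (0.99 to 8.92). In principal cells Ifit2 stood at 1.45, but the chemokine gene Cxcl10 at −2.97. Cholesterol synthesis genes were higher in the thin limb (0.66, with 21 higher and 0 lower), with the isoprenoid synthesis gene Fdps at 1.31, and in macrophages (0.69), led by Dhcr7 (2.42). The distal convoluted tubule had higher glycolysis genes (0.47, 15 higher and 0 lower), with the lactate dehydrogenase gene Ldha at 365 and 143 CPM (1.35), and a lower p53 list (−0.30), with Btg2 at 233 and 660 CPM. Btg2 is shared with the immediate early list, which was lower in this class too.

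In parietal epithelium-like cells MHC class II genes were higher (0.85, 6 higher and 0 lower), although the make-up of this class differed, with a T cell-like subcluster of 2 and 21 cells and a stromal-like one of 31 and 20. The injury gene Havcr1 had 51 and 0 UMIs there, held by 2 of 85 PT I-PpoI cells, of which 1 lay in a subcluster led by PT genes such as Spp2 and Mep1a (13 and 12 cells) and 1 in a mixed subcluster (18 and 9 cells), so it was not assigned to parietal cells. Havcr1 had 24 and 0 UMIs in intercalated cells. How many cells held these was not counted, so they are not read as a trait of intercalated cells. Of named cells outside the PT, podocytes, the filter epithelium, were 0.993% and 0.340%, urothelium 1.70% and 0.321%, fibroblasts 0.728% and 0.378% and cycling cells 0.750% and 0.359%, while B cells (1.04% and 2.61%) and natural killer cells (0.265% and 1.76%) were smaller shares in PT I-PpoI. The monocyte-drawing chemokine gene Ccl8 stood at 487 and 74.7 CPM in macrophages (2.70). The chemokine gene Ccl20 had 1 and 62 UMIs in the connecting tubule, −6.81 (−12.71 to −4.85).

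Y-linked genes were read in both libraries, with Ddx3y at 51.6 and 48.9 CPM and Eif2s3y at 46.7 and 41.7 CPM in PT-like cells. Xist, which female cells express, had 6 and 6 UMIs over all barcodes. Both libraries thus read as male, which argues against a difference in sex between them. The RNA of shallow barcodes differed in make-up. The ribosomal RNA-like transcript Gm42418 took 12.5% and 39.98% of UMIs in the ambient ranks, 8.19% and 5.11% in barcodes of 100 or fewer UMIs and 3.67% and 12.1% of all UMIs. Kap took 0.0400% and 1.14% of UMIs in barcodes of 100 or fewer UMIs, and thick ascending limb markers 1.13% and 0.171%.

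Lower fatty acid oxidation genes in PT-like cells were weighed against 3 explanations. Another mix of PT clusters as the whole cause is argued against only weakly. The median was −0.18 within cluster 14, at percentile 0 of random lists, with the criterion set after the values were known. Random lists draw genes singly, so this percentile does not allow for genes that move together. Free RNA of the wild-type library is argued against too, as the cluster 14 median was −0.27 (−0.60 to −0.02) after subtraction, also at percentile 0. Another mix of segments within cluster 14 cannot be told apart, because markers of the second segment had a median of −1.80 there, which a shift of segments or a lower level of these genes could both give. A hypothesis left untested is that PT cells surviving DNA breaks hold fewer transcripts for fat use, which spatial staining of Cyp4a14 beside segment markers in several animals would test.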
